A study of Rattus norvegicus with 6 samples.

How the data were processed

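RNA-seq was done on dorsal tongue epithelium of rats, which the series describes as tissue of the circumvallate papilla, the structure at the back of the tongue that holds taste buds. There were 3 libraries from rats without periodontitis (control) and 3 from rats with chronic periodontitis, a long-lasting inflammatory disease of the tissue around the teeth. Each group was taken from the disease label, and replicates were numbered 1 to 3 as in the titles. The labels do not say that each library is a separate animal, so the limma p-values of single genes measure the spread between these libraries, which may be partly technical. No 2 libraries held the same values.

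The deposited values are FPKM, mapped fragments scaled by the length of the transcript and the size of the library, per the file headers, with 1 value for each of 14405 protein-coding genes in each library. Adapter trimming with cutadapt, quality checks with FastQC, alignment with HISAT2 and assembly with StringTie are named in the submitters' processing notes by tool only, and tool versions are not given in the sources used here. Those notes name the mouse build mm10, whereas the identifiers and chromosomes in the deposited tables are those of rat, so positions below are as the tables give them and the rat build is not given in the sources used here. Read counts, depth and strand are not given either, so no counting interval or detection floor was computed, and a gene with no signal is described as listed at 0. FPKM is relative to each library's total, so a highly expressed tissue part lowers the values of all other genes. Reads of near-identical copies, such as the alpha globin, Hspa1a and Hspa1b, ribosomal protein and immunoglobulin genes, can be divided between copies by the authors' assembly and are uncertain one by one.

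From these values, log2(FPKM + 1) was computed without further scaling. Genes with at least 1 FPKM in at least 3 libraries were tested (13154 genes, with 1251 left out). The design written before the data were examined named limma with a mean-variance trend for normalized values, and this was used with group as the only term. The test was two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are periodontitis minus control on the log2(FPKM + 1) scale, which understates changes of low genes. R 4.3.3 and limma 3.58.1 were used. In 20 simulated data sets of the periodontitis against control comparison, each with 13154 genes of which 200 were changed, limma recovered 27.7% of genes changed 2-fold, 90.9% of those changed 4-fold and 98.6% of those changed 8-fold. It called 0.0691% of unchanged genes. The changed genes were drawn only from genes whose control mean, on the log2(FPKM + 1) scale, was above that of 5 FPKM. Recovery of lower genes was not simulated. The simulated noise was independent between genes and had the same spread in both groups. In the data, the periodontitis libraries correlated less with each other than the controls did. The recovered shares may therefore not hold for these data.

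A set of 41 gene lists for cell types and pathways was fixed before the data were examined. Lists with at least 3 tested genes (39 lists) were tested with camera at a preset correlation of 0.01 between genes. That setting takes the genes of a list as nearly independent. Its p-values therefore rest mainly on the spread between genes and do not measure the spread between libraries. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, while fry asks only whether a list's genes move. The rule for naming genes was also fixed in advance. Where fewer than 5 genes passed, it took the 10 genes with the smallest p, then 15 key genes of taste tissue and inflammation, and up to 4 genes with the smallest p in each list. Pkd2l1 and Tnf, which are key genes, were not analysed here. Genes named outside this rule are said to be chosen after their values were seen.

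Alternatives were the replicate number as a block, each library left out in turn, no filter, a mean of at least 5 FPKM, quantile normalization, limma without the trend, a pseudocount of 0.1 and other thresholds. After the data were seen, 2 more were added. They rescaled the libraries without 4 abundant gland genes, and compared periodontitis replicate 2 alone with the controls. Weights for single libraries were tried and not used because the estimate did not converge.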

Results

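Gene expression in tongue epithelium with the circumvallate papilla was measured in 3 control libraries and 3 libraries from rats with chronic periodontitis. The FPKM values of the 14405 listed genes summed to between 611713 and 660619 per library, and the sequencing depth behind them is unknown. Pearson correlations of log2 values were 0.966 to 0.980 between control libraries and 0.893 to 0.957 between periodontitis libraries. Pairs from different groups had correlations of 0.924 to 0.978. The 4 most abundant genes of the serous von Ebner glands (Lipf, Lcn1, Vegp2 and Bpifb1) made up 25.1%, 24.5% and 29.4% of the FPKM sum in controls 1 to 3. In periodontitis 1 to 3 they made up 15.2%, 23.5% and 40.6%. The first principal component held 52.2% of the variance and put periodontitis 1 (54.5) and periodontitis 3 (-42.9) at opposite ends, with periodontitis 2 (5.84) among the controls.

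The first comparison asked which single genes differed between periodontitis and control tissue. Among the 13154 tested genes, 0 passed an adjusted p of 0.05. The lowest p belonged to AABR07065656.3, a gene on chromosome 6 (138900522 to 138900915). It had 5.29 ± 1.63 FPKM in controls (SD, n = 3) and was listed at 0 in the 3 periodontitis libraries. Abo3, a homologue of the ABO blood group transferase on chromosome 3 (5118956 to 5126901), had 31.4 ± 15.6 FPKM in controls and 1.91 ± 1.49 FPKM in periodontitis (SD, n = 3). Defb5, which encodes a beta-defensin antimicrobial peptide, lies on chromosome 16 (75589530 to 75599534). It had 8.03 ± 2.90 FPKM in controls and 39.0 ± 19.5 FPKM in periodontitis (SD, n = 3).

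The log2 fold changes of these 3 genes were -2.62 ± 0.24 (SE, limma adjusted p = 0.0860) for AABR07065656.3, -3.49 ± 0.43 (adjusted p = 0.371) for Abo3 and 2.09 ± 0.36 (adjusted p = 1.0) for Defb5. RGD1565472 was listed at 0 in the 3 controls and had 2.01, 2.21 and 1.60 FPKM in periodontitis 1 to 3. The log2 fold change was 1.09 for Apold1. Lower values were seen for Mlf1 (-1.20), AABR07065750.2 (-2.54), Wisp2 (-0.90) and for the muscle genes Cacng1 (-1.14) and Actc1 (-1.21). In each of these 10 genes all 3 periodontitis libraries lay on one side of all 3 controls, but none passed the threshold. Over all tested genes, 731 had groups without overlap (5.56%, against 10% by chance). limma gave 278 genes with an unadjusted p under 0.05 (50 higher and 228 lower), where 658 would be so by chance. With control 1 left out, 1 gene passed (Fam111a, log2 fold change -4.27, adjusted p = 0.0163, chosen after its values were seen).

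**Figure D1:**
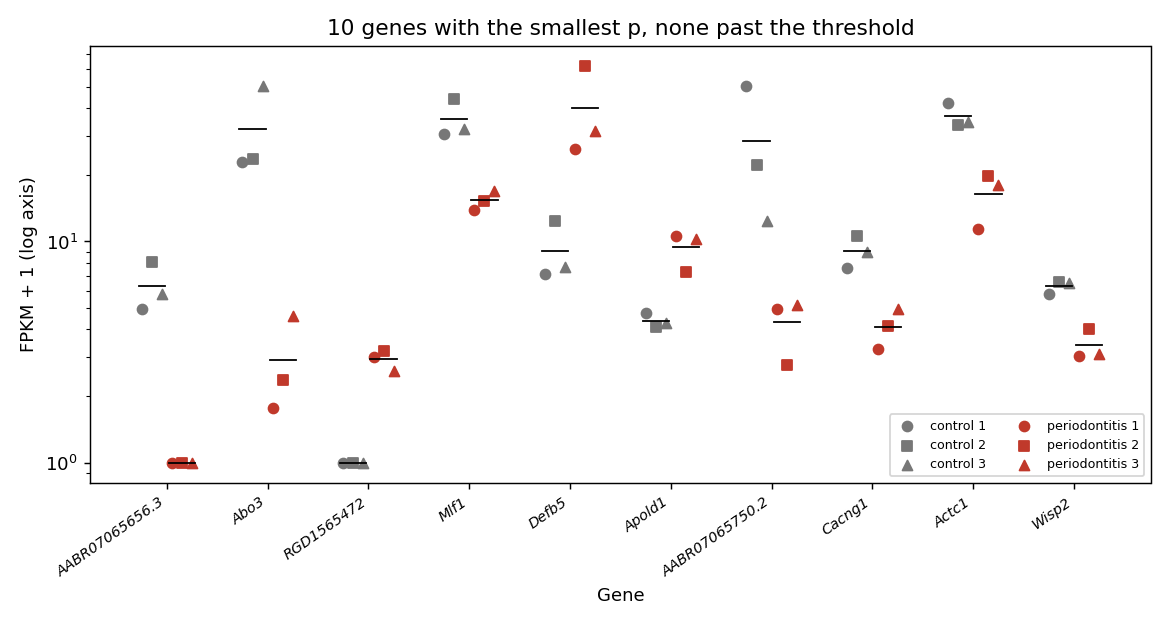
FPKM + 1 on a log axis for the 10 genes with the smallest p, with 1 point per library, grey for control and red for periodontitis, and a black line at the mean FPKM + 1 of each group. In each gene the 3 periodontitis points lie on one side of the 3 control points, yet 0 genes passed the adjusted threshold.

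The tested key genes of taste tissue had overlapping groups. Tas1r2, a subunit of the sweet receptor, had 7.22 ± 0.518 FPKM in controls and 9.48 ± 5.23 FPKM in periodontitis (SD, n = 3), with 15.5 FPKM in periodontitis 1. Gnat3, the taste G protein gustducin, had 14.9 ± 1.95 and 14.3 ± 7.83 FPKM. The transduction genes Plcb2 and Trpm5 had log2 fold changes of -0.05 and -0.14. Entpd2, a marker of type I support cells, had -0.14. The progenitor genes Shh, Lgr5 and Sox2 had -0.12, -0.12 and -0.40, and the taste bud keratin Krt8 had -0.23. Il1b, an inflammatory cytokine, had -0.25. All had a limma adjusted p that rounded to 1.0. Tas1r1, Tas1r3 and Il6 were below the filter. Il6 had 5.41 FPKM in periodontitis 1, 0.697 in periodontitis 3, was listed at 0 in periodontitis 2, and had at most 0.557 FPKM in controls.

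**Figure D2:**
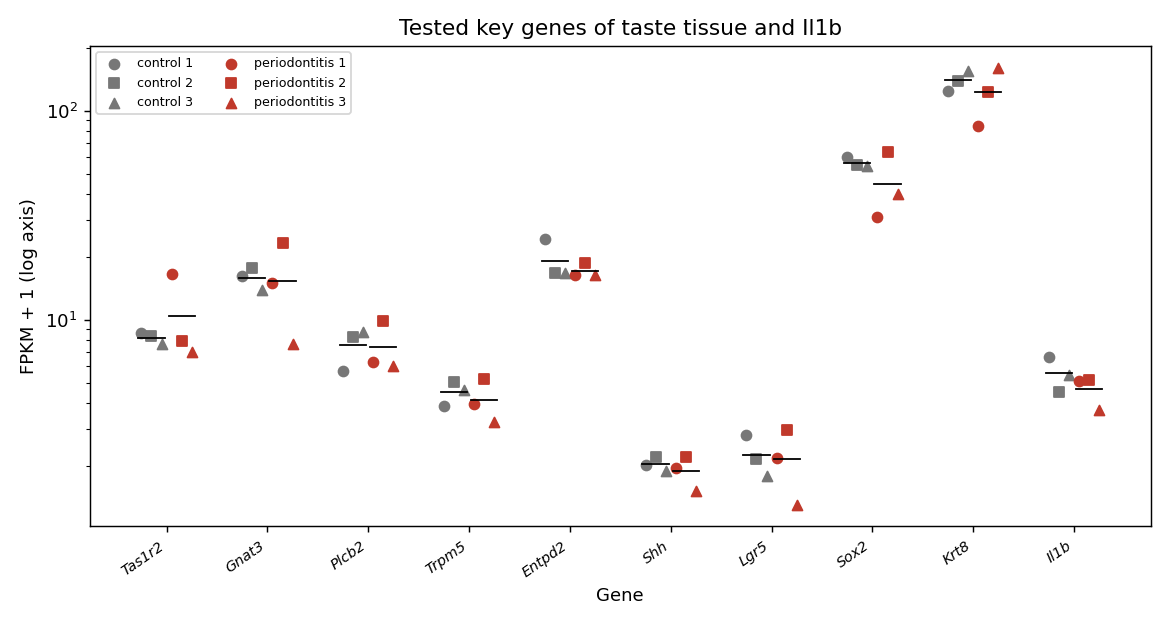
FPKM + 1 on a log axis for 10 tested key genes, with 1 point per library, grey for control and red for periodontitis, and a black line at the mean FPKM + 1 of each group. The 2 groups overlap in each gene, and Tas1r2 is highest in periodontitis 1 (15.5 FPKM).

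The second comparison asked which cell types and pathways differed as groups of genes. With the preset correlation, 12 of 39 lists passed, 3 higher and 9 lower in periodontitis. With an estimated correlation 0 lists passed (smallest adjusted p = 0.464), and with fry 0 passed (smallest adjusted p = 0.887). No list had a gene past the threshold over all genes.

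Immediate early genes, which are induced within minutes by many stimuli, were higher, with a median log2 fold change of 0.84 (camera adjusted p = 3.73e-19; adjusted p = 0.464 with an estimated correlation). Of the 17 tested, 16 had a higher mean in periodontitis and 7 an unadjusted p under 0.05. Egr1 had 24.6 ± 3.83 FPKM in controls and 73.8 ± 39.1 FPKM in periodontitis (SD, n = 3), and Dusp1, Zfp36 and Atf3 had log2 fold changes of 1.16, 1.21 and 2.71. The list medians, relative to the control mean, were 1.49 in periodontitis 1 and 1.04 in periodontitis 3. Periodontitis 2 had 0.19, within the control range of -0.27 to 0.35. Periodontitis 1 and 3 also had the most genes listed at 0 (218 and 174), against 72 to 124 in controls and 71 in periodontitis 2. The list median ranged from 0.61 without periodontitis 1 to 1.27 without periodontitis 2.

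Heat shock and unfolded protein genes were higher (median 0.14, mean 0.40, camera adjusted p = 5.87e-05; adjusted p = 0.712 with an estimated correlation). Of 19 tested, 14 had a higher mean and 3 had an unadjusted p under 0.05. The heat shock protein genes Hspa1a and Hspa1b had log2 fold changes of 1.49 and 1.37. Atf3, a stress transcription factor also in the immediate early list, had 2.71. The list medians were 0.43 and 0.37 in periodontitis 1 and 3, as with the immediate early genes the highest libraries, and -0.00273 in periodontitis 2, within the control range of -0.04 to 0.03. Without periodontitis 3 the list did not pass, although its median was 0.20 (adjusted p = 0.111). The median was 0.07 without control 3, 0.08 without control 1 and 0.22 without control 2, where the list passed.

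Red blood cell genes were higher, with a median of 1.03 (camera adjusted p = 4.35e-08; adjusted p = 0.464 with an estimated correlation). Hbb, the beta globin gene, had 45.3 ± 8.24 FPKM in controls and 138 ± 99.3 FPKM in periodontitis (SD, n = 3). The 3 tested globin rows had all 3 periodontitis libraries above all 3 controls, and 3 passed when adjusted over the list alone, with 0 over all genes. These rows, Hbb and copies of Hba-a2, had an estimated correlation of 0.88 between them, so they are not separate signals. The list median ranged from 0.68 without periodontitis 3 to 1.27 without periodontitis 2.

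Skeletal muscle genes were lower, with a median of -0.996 (camera adjusted p = 3.73e-19; adjusted p = 0.712 with an estimated correlation). All 21 tested had a lower mean in periodontitis, 13 had all 3 periodontitis libraries below all 3 controls and 9 had an unadjusted p under 0.05. Eno3, the muscle enolase, had 211 ± 42.9 FPKM in controls and 98.9 ± 48.7 FPKM in periodontitis, and Mb, myoglobin, had 863 ± 130 and 429 ± 214 FPKM (SD, n = 3). The list median was -1.96 in periodontitis 1, -0.65 in periodontitis 2 and -0.39 in periodontitis 3. With each library left out in turn the list passed each time, and its median ranged from -1.26 without periodontitis 3 to -0.50 without periodontitis 1.

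Fibroblast and matrix genes were lower (median -0.64, camera adjusted p = 8.28e-10; adjusted p = 0.712 with an estimated correlation), and all 15 tested had a lower mean. Sparc and Col3a1 had log2 fold changes of -0.68 and -0.99. Complement and acute phase genes were lower (median -0.80, camera adjusted p = 3.19e-08; adjusted p = 0.761 with an estimated correlation), with 14 of 15 lower in the mean. C3 and Cfi, components of the complement system, had -1.26 and -1.62. Both lists passed with each library left out in turn, but their medians moved. The fibroblast median ranged from -0.91 to -0.37 and the complement median from -1.20 to -0.36, in each case lowest in size without periodontitis 1 and highest without periodontitis 2.

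Lists of Schwann cells (median -0.43), mast cells (-0.61), antigen presentation (-0.37), macrophages (-0.38), matrix degradation (-0.34) and interferon response (-0.28) were lower with the preset correlation. Their adjusted p with an estimated correlation was 0.804 for mast cells and 0.824 for the others. None of the 6 passed without periodontitis 1, where their camera adjusted p was 0.739, 0.0997, 0.575, 0.580, 0.0599 and 0.124 in that order. Their medians there were -0.18, -0.30, -0.13, -0.13, -0.30 and -0.16. Matrix degradation also did not pass without control 1 (median -0.11, adjusted p = 0.419) or periodontitis 3 (-0.29, 0.269). Macrophages did not pass without control 1 (-0.25, 0.149). Interferon response did not pass without control 3 (-0.17, 0.198) or periodontitis 3 (-0.15, 0.0720), or among genes with a mean of at least 5 FPKM (-0.17, 0.140). A lower mean was seen in 13 of 13 Schwann cell, 8 of 8 mast cell, 14 of 16 antigen presentation, 12 of 14 macrophage, 8 of 10 matrix degradation and 18 of 22 interferon response genes. Examples were Pmp22 (-0.84), Tpsab1 (-0.69), RT1-Da (-0.76), Tyrobp (-0.37), Mmp2 (-0.66) and Ifi27 (-0.34), while Cx3cr1, a chemokine receptor in the macrophage list, had 0.49.

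**Figure D3:**
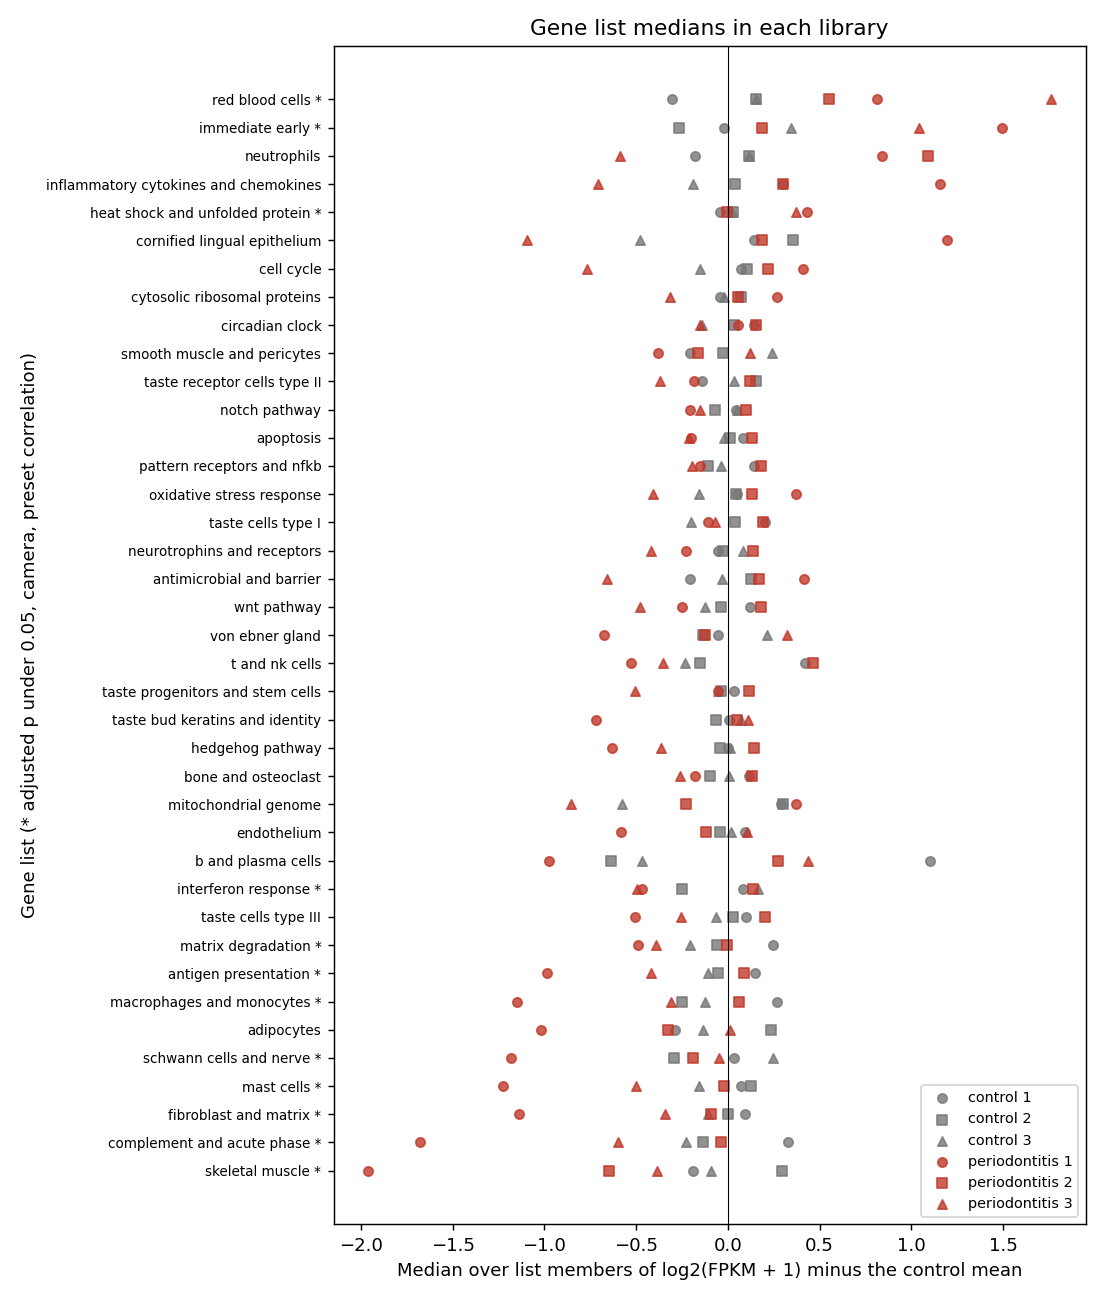
Median over list members of log2(FPKM + 1) minus the control mean, with 1 point per library, for the 39 tested lists, in order of their median log2 fold change. Lists with an asterisk passed camera with the preset correlation. Periodontitis 1 has the lowest skeletal muscle median (-1.96), and periodontitis 1 and 3 have the highest immediate early medians (1.49 and 1.04).

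The taste cell lists did not pass. Their medians were -0.05 for type II cells, -0.32 for type III cells, -0.09 for type I cells, -0.19 for taste bud keratins and -0.12 for progenitors. With 1 library left out, all but type III changed sign in some fits. Medians ran from -0.25 to 0.08 for type II and -0.65 to -0.13 for type III. They ran from -0.25 to 0.04 for type I, -0.43 to 0.02 for keratins and -0.24 to 0.04 for progenitors. Examples were Calhm3 (-0.32), Krt7 (-0.53), Syt1 (-0.25) and Cldn4 (0.49). All 3 periodontitis libraries lay below all 3 controls for Syt1 and above them for Cldn4, and neither gene passed. Without periodontitis 2, the type III list passed (median -0.65, adjusted p = 0.00606), as did Wnt (median -0.18) and Hedgehog (-0.38) lists. With an estimated correlation or fry, 0 lists passed in that fit. With all libraries, the Wnt, Hedgehog, Notch and neurotrophin lists had medians of -0.11, -0.20, -0.07 and -0.09. Of 12 bitter receptor genes, 2 were tested, too few for a list test.

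The other lists did not pass with all 6 libraries and group as the only term. Cytokines and chemokines had a median of 0.15, and Cxcl1, a neutrophil attractant, had 8.30 ± 1.51 FPKM in controls against 105, 9.73 and 36.3 FPKM in periodontitis 1 to 3. Cxcl6, another chemokine, had a log2 fold change of -0.94. The cytokine list medians were 1.16, 0.30 and -0.71 in periodontitis 1 to 3, and the list's median log2 fold change was -0.27 without periodontitis 1 and -0.06 without periodontitis 2. The 4 tested neutrophil genes had a median of 0.43, which ranged from 0.10 without periodontitis 2 to 0.97 without periodontitis 3, and passed without control 2 (0.50) or periodontitis 3. Of these genes, S100a9 (1.06), S100a8 (0.80) and Lcn2 (-0.05) are also in the antimicrobial list of epithelial genes. The other, Cxcr2, had 0.07. S100a9 had 99.7, 255 and 27.5 FPKM in periodontitis 1 to 3, against 33.5 to 54.8 FPKM in controls. The antimicrobial list had a median of -0.11, and Defb5 was the 1 gene of it that passed when adjusted over the list alone. Cornified epithelium had a median of 0.10 and von Ebner gland -0.11. Without periodontitis 3, lists of cornified epithelium (0.64), cell cycle (0.33), antimicrobial genes (0.25) and cytokines (0.57) passed as higher. Cytokines also passed without control 1 (0.16), and cornified epithelium without control 2 (0.29). Without periodontitis 1, cornified epithelium (-0.44) and cell cycle (-0.26) passed as lower. Each of these passes was with the preset correlation, and with an estimated correlation or fry 0 lists passed in the same fits. Median, mean and test differed in sign for type I taste cells, von Ebner gland, pattern receptors, antimicrobial, cell cycle, circadian and ribosomal lists.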

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

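The gland rescaling and periodontitis 2 alone were chosen after the data were seen. The count of genes (0) moved to 3 with the replicate number as a block, 1 higher and 2 lower (Defb5, adjusted p = 0.0227; Abo3, 0.000974; AABR07065656.3, 0.0302), and the 12 lists to 15, with endothelium, adipocytes and neutrophils added. The numbers do not pair the libraries by the rule used, since deviations of equal numbers correlated at 0.09, 0.03 and 0.46, and of the 3 numbers only libraries of number 3 correlated best with their own. Leaving out each library gave 0 to 1 genes, 0 to 1 lower, and 11 to 18 lists, 3 to 8 higher. An adjusted p under 0.1 gave 1 gene, lower. Periodontitis 2 alone is 1 library with no spread of its own, assumed to vary like the controls, so its counts describe that library. It gave 1 gene, higher (ENSRNOG00000030174), and 7 lists, 5 lower, of which 3 were among the 12, and moved the median of all genes by 0.13. An estimated correlation and fry gave 0 lists, 0 higher and 0 lower. The other settings gave 0 genes and 12 to 13 lists. Where a list reversed, medians were -0.44 for cornified epithelium, -0.26 for cell cycle and -0.13 for ribosomal proteins without periodontitis 1 (0.64, 0.33 and 0.16 without periodontitis 3), 0.25 for B and plasma cells without control 1 (-0.53 without periodontitis 3), and -0.003 (-0.00273) for heat shock with periodontitis 2 alone. Fewer libraries enter these fits, and the cause was not tested further. Over the values of 167 named genes in these fits, 3 became past the threshold and 0 reversed. At most 100 moved by more than the spread, a count that also holds changes in the number of lists. A reversal was counted only where the gene passed in 1 of the fits compared. Changes of sign in genes that did not pass were therefore not counted. Depth is unknown, so its limit on low genes could not be given.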

Other observations

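Several lists showed differences between libraries that did not follow the groups. The cornified epithelium median was 1.20 in periodontitis 1 and -1.09 in periodontitis 3, between which all controls lay (-0.48 to 0.35). Krt10, a keratin of differentiated epithelium, had 642 FPKM in periodontitis 1 and 76.7 in periodontitis 3. Over 6 libraries the cornified median was inversely related to the von Ebner gland median (Pearson r = -0.97, exact permutation p = 0.00139, adjusted p = 0.0111; Spearman rho = -1, exact permutation p = 0.00278, adjusted p = 0.0222), and without periodontitis 1 and 3 r was -0.99 over 4 libraries. The cytokine median went with it (Pearson r = 0.96, exact permutation p = 0.0111, adjusted p = 0.0296; Spearman rho = 0.77, exact permutation p = 0.103, adjusted p = 0.206), with r = 0.70 without these 2 libraries. The 8 relations computed were chosen after the data were seen. The medians of complement (r = -0.42), interferon (-0.09), antigen presentation (-0.35) and macrophage lists (-0.49) had exact permutation adjusted p of 0.52 to 0.86 (Spearman adjusted p = 0.919). Cell cycle had r = 0.94 (exact permutation adjusted p = 0.0167; Spearman rho = 0.94, adjusted p = 0.0667), with r = 0.87 without these 2 libraries. Antimicrobial genes had r = 0.89 (exact permutation adjusted p = 0.05; Spearman rho = 0.89, adjusted p = 0.0889), which rests on these 2 libraries, with r = 0.32 without them. All values are shares of a library total. With libraries rescaled without the 4 abundant gland genes, and these left out of the gland list, r with the gland was -0.96 (exact permutation p = 0.00417; Spearman rho = -0.94, exact permutation p = 0.0167), and -0.80 without periodontitis 1 and 3.

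Other lists that did not pass had medians of -0.24 for B and plasma cells, -0.12 for T and NK cells, -0.41 for adipocytes, -0.22 for endothelium, -0.03 for smooth muscle, -0.20 for bone and osteoclast, -0.07 for apoptosis, -0.08 for oxidative stress, -0.07 for pattern receptors, -0.02 for circadian clock, -0.22 for the mitochondrial genome, 0.006 (0.00633) for cell cycle and 0.004 for ribosomal proteins. Some of them passed in other fits at the preset correlation, while 0 lists passed there with an estimated correlation or fry. Endothelium passed without control 2 (-0.28) or periodontitis 3 (-0.43), among genes with a mean of at least 5 FPKM (-0.20) and with a pseudocount of 0.1 (-0.24), and adipocytes without control 1 (-0.59) or periodontitis 3 (-0.60). Mitochondrial genes passed without control 3 (-0.55) or periodontitis 1 (-0.57), T and NK cells without periodontitis 2 (-0.43), and smooth muscle without periodontitis 3 (-0.26). Oxidative stress (-0.26) and ribosomal proteins (-0.13) passed without periodontitis 1, ribosomal proteins without periodontitis 3 (0.16), and B and plasma cells without control 1 (0.25). Ctsk, a protease of osteoclasts and fibroblasts, had -0.87 with all 3 periodontitis libraries below all 3 controls. Gsta1, a glutathione transferase, had 17.9 ± 0.162 FPKM in controls and 9.52 ± 5.10 FPKM in periodontitis (SD, n = 3). In the von Ebner gland list, Lpo, lactoperoxidase, had 2.32 ± 0.611 and 8.09 ± 6.14 FPKM, and Bpifa2 had 29.3 ± 22.2 and 10.3 ± 4.65 FPKM. Kdm5d and Eif2s3y, on the Y chromosome, were present in all 6 libraries (4.98 to 8.95 and 27.1 to 38.6 FPKM).

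All tests of explanations in this part were chosen after the results were seen. Immediate early genes were higher in periodontitis 1 and 3. These libraries lie on opposite sides of the controls for cornified epithelium. If a different share of surface epithelium and gland were the whole source, they should lie apart here too. The lower of their immediate early medians was 1.04, above the highest control (0.35) by more than the control SD (0.31). The list was chosen because it was higher in periodontitis, which favours high medians in both libraries, so this cannot exclude that source. Shares of other tissue parts, such as muscle, were not compared with this list. Handling before the RNA was preserved may contribute and cannot be told apart from periodontitis, because 2 of 3 periodontitis libraries lay above the controls and no handling record was used here. Periodontitis as the source stays open, with an exact permutation p of 0.2 for the library medians (two-sided, n = 3 and 3), where 0.1 is the smallest possible.

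Skeletal muscle genes were lower in periodontitis. Muscle was compared with the median of the fibroblast, smooth muscle, endothelium, Schwann cell and fat lists. Muscle minus that median was lower in periodontitis by a log2 difference of -0.61 ± 0.24 (SE). It was -0.94, -0.49 and -0.40 in periodontitis 1 to 3, and -0.23, 0.32 and -0.11 in controls 1 to 3. Muscle had the lowest median log2 fold change of the tested lists, so a gap below other lists could follow from choosing it. The gap therefore cannot decide whether less underlying tissue of every kind was the whole source. Fewer muscle fibres in the piece taken may account for the lower muscle genes, since 21 of 21 tested genes had a lower mean. Lower muscle expression would give that too, so these cannot be told apart. Periodontitis itself stays open, with an exact permutation p of 0.1 (two-sided, n = 3 and 3), the smallest possible. As muscle was chosen as the lowest of the tested lists, this p too could follow from the choice.

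AABR07065656.3 and AABR07065750.2 lie among 69 listed genes of the immunoglobulin heavy chain locus on chromosome 6 (138054662 to 143702033), a region chosen after its values were seen, and of 39 tested, 30 had a lower mean in periodontitis (median -0.45, camera p = 4.29e-10 with the preset correlation, p = 0.0561 with an estimated one, fry p = 0.109). These tests include the 2 genes that led to the region, and for periodontitis, not weighed further, the exact permutation p of the library medians was 0.3 (two-sided, n = 3 and 3). Fewer plasma cells may contribute and cannot be told apart. The median of 6 plasma cell genes lay 0.15 above that of the locus, while Igh-6 had a log2 fold change of 0.71. Igh-6 and Ighg, counted among the plasma cell genes, are themselves heavy chain genes, so the compared sets may overlap. The small gap of 0.15 rests on control 1, without which the plasma cell median was 0.25 and the locus median -0.31. Without control 2 the plasma cell and locus medians were -0.51 and -0.68, and without control 3 they were -0.58 and -0.74. Antibody clones that differ between animals whatever their group stay possible. In 2 of 3 periodontitis libraries, not all, the locus median lay below the lowest control. Most other sources could give that too, so it cannot decide.

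Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 genes and the highest other 1. No split can call fewer than 0 genes, so all 10 reach the real count by construction and the count of genes tests nothing. The real split gave 12 lists and the highest other 17, with 7 of 10 splits giving as many.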
